A study of Mus musculus with 4 samples.

How the data were processed

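RNA was measured in 4 subcutaneous tumors grown in nude mice from immortalized baby mouse kidney epithelial cells (iBMK) that lack the autophagy gene Atg5 and express Bcl-2. The cells of 2 tumors expressed EGFP, a green fluorescent protein, and those of the other 2 expressed p62 (the product of Sqstm1) fused to EGFP. Each tumor was hybridized to 1 Affymetrix Mouse Genome 430A 2.0 array as biotin-labelled cRNA, per the labels' protocols. The deposited values are 1-colour signal intensities on a linear scale, and MAS5 is named for them in the submitters' processing notes, with version and settings not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 150.04 on every array, so the authors' values were already scaled between arrays and were used as deposited. The rule fixed beforehand kept them as deposited if these means lay within 10% of each other.

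The table held 22690 probe sets, of which 64 were Affymetrix controls and were left out of the tests. Genes were named through the array annotation supplied with the data. Of the remaining 22626 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none; no gene was named from a probe set with several symbols or none. The Entrez identifier of 20364 single-symbol probe sets matched the reference gene table of assembly GRCm38.p6, and 0 symbols changed. No genome build is given for the array values, so that table was used only for gene names, chromosome assignment and gene order, and no coordinates are printed. Of 12393 genes, 4956 had more than 1 probe set, and a gene was represented in gene list tests by its probe set of highest mean.

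Signals were transformed as log2(signal + 16), and a fold change on this scale understates the change of dim probe sets. A probe set was tested if its mean over the 4 arrays was at or above the 40th percentile, a log2 value of 5.60, which left 13576 probe sets of 7847 genes. The p62-EGFP tumors were compared with the EGFP tumors with lmFit and eBayes (trend = TRUE) of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The series' design text names a selection of genes with Genes@Work at a significance level of 0.05, which was not installed here, and limma took its place. The list of genes selected by the submitters was not used here.

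Before the data were examined, 36 gene lists were fixed: 22 pathways, 12 host cell types and 2 reference lists of ribosomal protein and immediate early genes. The 32 lists with at least 5 tested members were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The genes named in the text also followed a rule fixed beforehand. They are Sqstm1, Atg5 and Bcl2; up to 12 genes per direction past the threshold with non-overlapping arrays, ranked by fold change; and the 4 members of each list with the smallest p. Clone and predicted-gene names were passed over, and a direction with fewer than 12 genes past the threshold was filled by the smallest unadjusted p. Genes named outside this rule are said to have been chosen after their values were seen.

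The same limma fit was checked on 10 simulated sets of arrays drawn for the comparison of p62-EGFP with EGFP tumors over 13576 probe sets, 200 of them changed. It recovered 10.5% of changes of 2-fold, 78.3% of 4-fold and 92.5% of 8-fold, and 4.65% of its calls were false. Camera with the preset correlation recovered 20 of 20 simulated lists shifted by 0.5 on the log2 scale and called 0 of 300 others. With an estimated correlation it recovered 0 of the 20. The simulated probe sets varied independently of each other and with the same spread in both groups. In the data the replicate difference had an SD of 0.604 for EGFP and 0.273 for p62-EGFP tumors. These counts therefore do not show how either correlation setting performs where the genes of a list move together.

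Alternatives covered array scaling (quantile normalization, median centring), the pseudocount (1 and 64), the filter (none, 60th percentile), the variance model, a replicate block, averaging the probe sets of a gene, and leaving out each tumor in turn. Subtracting chromosome medians was added after the data were seen. Figures and the tests of chromosomes and host cells were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 4 arrays limit the precision: 2 against 2 leave 2 residual degrees of freedom, and an exact two-sided test of a single value cannot go below p = 0.333. The labels do not say whether the 2 tumors of a group came from separate mice or cultures. The limma p-values of single probe sets therefore measure the spread between these tumors only. Those of camera with the preset correlation and of the chromosome permutations compare genes with other genes. However small, they are not a measure of how much tumors of a group vary.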

Results

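Gene expression was compared between tumors of autophagy-defective kidney epithelial cells that expressed p62-EGFP (2 tumors) and tumors of the same cell background that expressed EGFP alone (2 tumors). p62 is an adaptor protein that autophagy degrades, and the comparison asks which transcripts differ when it is expressed in excess in tumors without Atg5. All values are scaled MAS5 signals given as mean ± SD of 2 tumors unless stated otherwise. The median signal was 60.8 and 60.9 on the EGFP arrays and 57.7 and 59.9 on the p62-EGFP arrays. The ratio of 3' to 5' signal, a measure of RNA integrity, was 0.709 and 0.740 for Gapdh in the EGFP tumors and 0.707 and 0.720 in the p62-EGFP tumors. For Actb it was 1.39 and 1.28 against 1.37 and 1.55. The p62-EGFP tumors resembled each other more closely (r = 0.980 across tested probe sets, which are not independent replicates) than the EGFP tumors did (r = 0.901). Between groups r ranged from 0.893 to 0.946, so the EGFP tumors differed from each other as much as from some p62-EGFP tumors.

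Sqstm1, which encodes p62, had a signal of 1066 ± 127 in the EGFP tumors and 1560 ± 180 in the p62-EGFP tumors (n = 2 each). Both p62-EGFP tumors lay above both EGFP tumors, with a log2 difference of 0.54 (SE 0.14). The difference did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.235), and it is not known whether this probe set detects the transgene. Sqstm1 lies on chromosome 11, whose 697 genes had a median log2 difference of 0.30, so part of its difference can be shared with that chromosome. Atg5, the gene deleted in these cells, was measured by 3 probe sets, with log2 differences of -0.22, -0.21 and -0.27 that did not pass (limma adjusted p = 0.574, 0.643 and 0.523). Its brightest probe set gave 111 ± 11.2 in EGFP and 92.6 ± 1.84 in p62-EGFP tumors. Where the probes lie relative to the deleted part is not given in the sources used here. The Bcl2 probe set read 5.4, 15.2, 5.6 and 2.4 in EGFP tumors 1 and 2 and p62-EGFP tumors 1 and 2, and was too dim to be tested.

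The gene with the largest rise in the p62-EGFP tumors was Xist, the noncoding RNA that coats the inactive X chromosome. It went from 24.2 ± 14.8 in the EGFP tumors to 3642 ± 109 in the p62-EGFP tumors, a log2 change of 6.56 (SE 0.28, limma adjusted p = 0.00601). The other 2 Xist probe sets rose as well, by 7.40 and 4.35 on the log2 scale (limma adjusted p = 0.00319 and 0.00601). Without p62-EGFP tumor 1 or tumor 2 the log2 change of Xist was 6.59 and 6.53, and the call was lost (limma adjusted p = 0.165 and 0.139). The other 244 genes of the X chromosome had a median log2 difference of 0.04. Cntn1, a neural cell adhesion molecule, rose from 4.75 ± 0.64 to 202 ± 32.5 (log2 change 3.39, limma adjusted p = 0.0157); with no filter on low values Cntn1 did not pass (limma adjusted p = 0.0875). Zcchc18 rose from 6.10 ± 2.97 to 116 ± 6.65 (limma adjusted p = 0.0485), and Tesc, which encodes the calcium-binding protein tescalcin, from 19.3 ± 2.26 to 142 ± 2.26 (limma adjusted p = 0.0495). Both of the last calls were close to the threshold: with a pseudocount of 64, Zcchc18 and Tesc did not pass (limma adjusted p = 0.0570 and 0.0628).

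In all, 8 probe sets rose and 4 fell among the 13576 tested, with limma and Benjamini-Hochberg adjustment. The 8 were the 6 probe sets of these 4 genes and 2 without a gene name, whose signals went from 212 ± 9.48 to 1025 ± 66.8 and from 82.0 ± 13.4 to 596 ± 36.4. None of the 4 that fell could be assigned to 1 gene. For 3 of them, each annotated with 5 genes, the signal went from 550 ± 51.5 to 7.55 ± 5.02, from 591 ± 61.0 to 15.9 ± 5.94 and from 436 ± 11.5 to 11.6 ± 4.53. For the fourth, annotated with 2 genes, it went from 2613 ± 279 to 831 ± 67.3. At an unadjusted p below 0.05, 1970 probe sets differed, 1186 higher and 784 lower, where chance alone gives 678.8. The arrays of the groups did not overlap, with p62-EGFP higher, for 26.7% of probe sets, and with p62-EGFP lower for 22.2%. Chance gives 16.7% each way. The count of 12 depended on the tumors in the fit: it was 0 without either p62-EGFP tumor, 2835 without EGFP tumor 1 and 1294 without EGFP tumor 2, and the last 2 take the spread from the p62-EGFP pair alone.

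Other genes had higher signals in both p62-EGFP tumors without passing the test. Sox2, a transcription factor of stem and progenitor cells, read 13.9 ± 9.90 in EGFP and 227 ± 87.1 in p62-EGFP tumors, and Hey1, a transcriptional target of Notch, 54.2 ± 8.06 and 297 ± 84.1. Lox, the collagen cross-linking enzyme lysyl oxidase, read 24.1 ± 1.70 and 116 ± 9.40, and C1qtnf3, a secreted C1q-related protein, 6.15 ± 1.34 and 109 ± 19.1. Acly, which makes cytosolic acetyl-CoA for lipid synthesis, read 598 ± 98.4 and 1420 ± 100.5. It lies on chromosome 11, whose 697 genes had a median log2 difference of 0.30. The noncoding RNA Snhg6 read 292 ± 27.9 and 784 ± 50.8, the kinase gene Ripk4 61.95 ± 2.62 and 183 ± 20.3, and the ribosomal protein gene Rps7 2649 ± 1.84 and 3885 ± 53.7. Their limma adjusted p-values ran from 0.0594 for C1qtnf3 to 0.150 for Ripk4.

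Other genes had lower signals in both p62-EGFP tumors and did not pass. The mast cell proteases Cpa3, Cma1 and Tpsab1 read 116 ± 12.7, 76.5 ± 8.41 and 230 ± 100.2 in EGFP tumors and 13.1 ± 3.89, 12.6 ± 2.47 and 26.2 ± 8.27 in p62-EGFP tumors. The immunoglobulin genes Ighm and Igkv8-30 read 285 ± 70.1 and 171 ± 104 against 48.0 ± 5.02 and 2.45 ± 2.47. As members of multigene families, their probe sets can bind related transcripts. The pericyte gene Rgs5 read 343 ± 33.9 and 138 ± 0.07, the receptor tyrosine kinase gene Axl 421 ± 56.4 and 167 ± 10.3, and the transporter gene Slco3a1 114 ± 6.58 and 32.6 ± 7.50. The limma adjusted p-values of these 8 genes ran from 0.0842 for Cpa3 to 0.161 for Axl and Slco3a1.

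**Figure D1:**
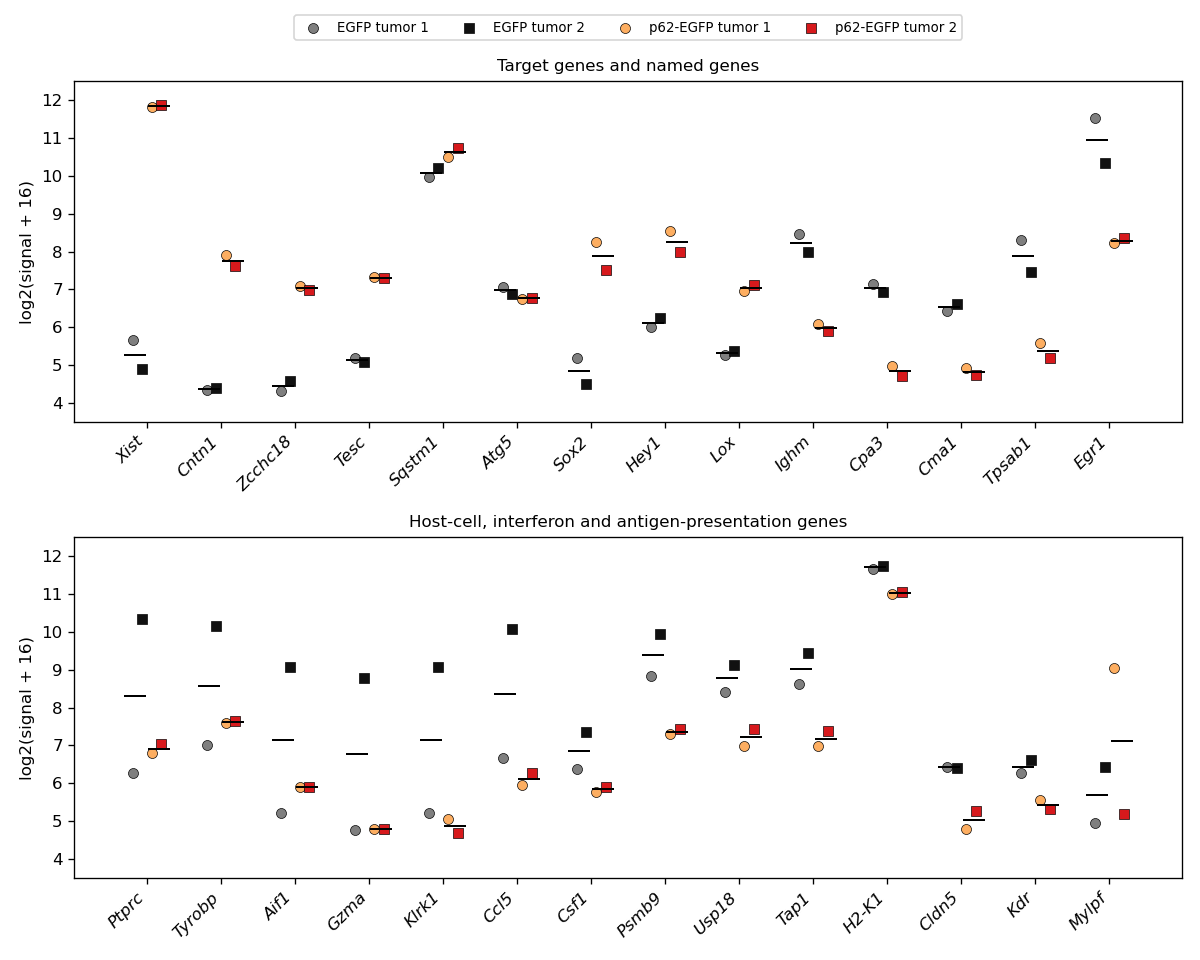
Signal of single genes in each tumor, as log2(signal + 16) on the vertical axis; each point is 1 tumor and each short line the mean of a group's 2 log2 values, for the probe set of highest mean. Xist read 24.2 ± 14.8 in EGFP and 3642 ± 109 in p62-EGFP tumors, and the immune cell genes Ptprc and Tyrobp stood at 1264 and 1111 in EGFP tumor 2 alone.

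Of the 32 gene lists tested, 8 were higher and 11 lower in p62-EGFP tumors (limma's camera, preset correlation of 0.01, adjusted over the lists). No member of any list passed the test over all probe sets, so counts of members below are adjusted over the list alone. With an estimated correlation between genes, 0 of the lists passed, and fry passed 0 after adjustment and 5 at an unadjusted p below 0.05.

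Genes of antigen presentation were lower in the p62-EGFP tumors, with a median log2 difference of -1.24 over 18 genes and 14 of them below both EGFP tumors. The call had a camera adjusted p of 6.04e-10 with limma's preset correlation and an adjusted p = 0.623 with an estimated correlation. Over the list alone 8 members were lower, among them H2-K1, an MHC class I heavy chain (3300 ± 115 against 2057 ± 64.3), and B2m, its light chain (3267 ± 0.64 against 2502 ± 45.7). Tap1, a subunit of the peptide transporter, read 525 ± 212 against 130 ± 29.3, and the immunoproteasome subunit Psmb9 698 ± 366 against 149 ± 10.4. MHC class I genes are closely related, and their probe sets can share signal. The interferon response list had a median of -0.93 over 32 genes, 16 of them below both EGFP tumors and 0 significant over the list alone (limma's camera, adjusted p = 8.68e-09 with the preset and adjusted p = 0.623 with an estimated correlation). Usp18, a brake on interferon signalling, read 435 ± 154 against 134 ± 31.8, and Irf9, a subunit of the interferon-activated transcription factor ISGF3, 175 ± 29.0 against 95.8 ± 15.1. Without EGFP tumor 2, in which the leukocyte gene Ptprc stood at 1264, the medians were -0.37 for antigen presentation and -0.27 for interferon response. Without EGFP tumor 1 the interferon response median was -1.61. Against EGFP tumor 1 alone, the antigen presentation medians were -0.44 and -0.31 in p62-EGFP tumors 1 and 2. The interferon response medians were -0.47 and 0.01, so p62-EGFP tumor 2 was not lower than EGFP tumor 1 for that list.

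Targets of NF-kB, a transcription factor whose upstream signalling p62 takes part in, were lower as a list, by a median of -0.74 over 20 genes. Limma's camera gave an adjusted p of 4.92e-05 with the preset correlation and an adjusted p = 0.623 with an estimated correlation. Both p62-EGFP tumors lay below both EGFP tumors for 9 of the 20, and 1 passed over the list alone, Psmb9. Tapbp, which loads peptides onto MHC class I, read 1436 ± 560 against 691 ± 98.7, the cytokine gene Csf1 107 ± 56.6 against 41.3 ± 3.89, and the Rel family gene Relb 117 ± 47.8 against 66.2 ± 12.8. The call rested on EGFP tumor 2: without it the median was -0.08 and the call was lost (limma's camera, adjusted p = 0.338), and without EGFP tumor 1 the median was -1.31 (limma's camera, adjusted p = 9.33e-18). Components of NF-kB signalling had a median of -0.20 over 25 genes, 11 of them below both EGFP tumors and 0 significant over the list alone (limma's camera, adjusted p = 0.0111, and adjusted p = 0.623 with an estimated correlation). The TNF receptor gene Tnfrsf1a read 403 ± 15.98 against 251 ± 10.5, the kinase gene Ikbkb 349 ± 10.5 against 252 ± 0.64, and Rela 615 ± 18.7 against 462 ± 29.3. This call was also lost without EGFP tumor 2 (median -0.06, limma's camera adjusted p = 0.587).

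Transcripts of macrophages stood high in EGFP tumor 2 and low in the other 3 tumors. Ptprc, the pan-leukocyte CD45, read 60.8 and 1264 in EGFP tumors 1 and 2 and 95.9 and 115 in the p62-EGFP tumors. Tyrobp, an adaptor of myeloid and NK cell receptors, read 113 and 1111 against 177 and 184, and Aif1 20.9 and 516 against 43.8 and 43.6. The median over 24 genes was -0.70, with 0 genes apart between groups and 0 significant over the list alone (limma's camera, adjusted p = 0.0230, and adjusted p = 0.743 with an estimated correlation). Without EGFP tumor 2 the direction turned, to a median of 0.73 (limma's camera, adjusted p = 4.88e-13). The list of complement and acute phase genes followed the same tumor, with a median of -0.69 over 13 genes and 1 lower over the list alone, Socs3, at 248 ± 60.7 against 105 ± 13.4 (limma's camera, adjusted p = 0.00369, and adjusted p = 0.623 with an estimated correlation). Cytokines and chemokines had a median of -0.73 over 14 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.0174, and adjusted p = 0.701 with an estimated correlation). The chemokine gene Ccl5 read 85.6 and 1056 in the EGFP tumors and 45.9 and 61.4 in the p62-EGFP tumors, whereas Cxcl12 read 801 and 450 against 274 and 214. The lysosome list had a median of -0.31 over 34 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.00366, and adjusted p = 0.701 with an estimated correlation), with Lamp1, a lysosomal membrane protein, at 1294 ± 207 against 844 ± 20.1. Without EGFP tumor 2 these 3 lists did not pass, with medians of -0.09, 0.36 and 0.09 (limma's camera, adjusted p = 0.788, 0.175 and 0.104). Without p62-EGFP tumor 1 the cytokine list did not pass either (limma's camera, adjusted p = 0.0610). NK and T cell genes did not pass (median -2.001 over 6 genes, 0 significant over the list alone, limma's camera adjusted p = 0.0662). Klrk1, an activating NK cell receptor, read 21.2 and 524 against 17.4 and 10.0. The NK and T cell list did pass in 6 settings that kept all tumors, among them the replicate block and no filter (limma's camera, adjusted p = 0.00728 and 2.11e-04). Its median was -3.93 without EGFP tumor 1, -1.90 without p62-EGFP tumor 1 and -1.99 without p62-EGFP tumor 2, and these fits all keep EGFP tumor 2. Without EGFP tumor 2 the list had too few tested genes for a test. The median difference of the p62-EGFP tumors was -0.04 against EGFP tumor 1 and -3.97 against EGFP tumor 2.

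Most mast cell and endothelial genes, 4 of 5 and 11 of 14, were lower in both p62-EGFP tumors than in either EGFP tumor. The mast cell list had a median of -1.69 over 5 genes, and 4 were lower over the list alone: Cpa3, Cma1, Tpsab1 and Mcpt2 (68.8 ± 38.3 against 18.9 ± 14.4). Limma's camera gave an adjusted p of 3.39e-04 with the preset correlation and an adjusted p = 0.623 with an estimated correlation. The endothelial list had a median of -0.74 over 14 genes, and 5 were lower over the list alone (limma's camera, adjusted p = 1.13e-05, and adjusted p = 0.623 with an estimated correlation). Cldn5, an endothelial tight junction protein, read 69.8 ± 1.41 against 17.1 ± 7.57, the cadherin gene Cdh5 58.5 ± 2.47 against 23.8 ± 2.55, and Kdr, a VEGF receptor, 71.5 ± 13.6 against 27.5 ± 5.02. The endothelial median was -0.45 without EGFP tumor 2 (limma's camera, adjusted p = 0.00733).

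Immediate early genes, which respond within minutes to growth factors and to tissue handling, were lower by a median of -1.07 over 19 genes. Limma's camera gave an adjusted p of 4.20e-07 with the preset correlation and an adjusted p = 0.623 with an estimated correlation. Over the list alone 7 members were lower, including Egr1 (2113 ± 1180 against 296 ± 18.7), Fos (1310 ± 1222 against 109 ± 11.1), Junb (325 ± 97.0 against 79.5 ± 10.7) and Zfp36 (270 ± 29.5 against 92.2 ± 18.2). EGFP tumor 1 had the highest levels, with Egr1 at 2948 and 1278 and Fos at 2174 and 446 in EGFP tumors 1 and 2. Without EGFP tumor 1 the median was -0.65 (limma's camera, adjusted p = 4.94e-05).

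Ribosomal protein genes were higher in the p62-EGFP tumors by a small margin, a median of 0.28 over 27 genes with 24 above both EGFP tumors. With quantile normalization of the arrays the median was 0.15 (limma's camera, adjusted p = 0.0162). Limma's camera gave an adjusted p of 2.67e-10 with the preset correlation and an adjusted p = 0.529 with an estimated correlation. Over the list alone 10 members were higher, including Rpl7 (2600 ± 74.2 against 3515 ± 14.1 in p62-EGFP tumors) and Rpl27 (3136 ± 113 against 4120 ± 41.2). Oxidative phosphorylation genes had a median of 0.18 over 43 genes, 21 above both EGFP tumors, 0 below and 0 significant over the list alone (limma's camera, adjusted p = 9.77e-05, and adjusted p = 0.623 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, read 1197 ± 105 against 1887 ± 15.3. Without p62-EGFP tumor 1 the median of the list was 0.10 (limma's camera, adjusted p = 0.00827). Skeletal muscle transcripts stood 19.01-fold higher in that tumor than in p62-EGFP tumor 2. Glycolysis and hypoxia genes had a median of 0.25 over 25 genes, and 3 were higher over the list alone (limma's camera, adjusted p = 0.00160, and adjusted p = 0.623 with an estimated correlation). The 3 were Lox, the glycolytic enzyme gene Pgk1 (1067 ± 194 against 2019 ± 126) and Egln3, a HIF prolyl hydroxylase (25.2 ± 2.19 against 58.2 ± 1.98). Without EGFP tumor 1 this median was 0.45 (limma's camera, adjusted p = 0.00801). Heat shock proteins had a median of 0.21 over 27 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.00279, and adjusted p = 0.623 with an estimated correlation), with the mitochondrial chaperonin Hspd1 at 989 ± 33.2 against 1362 ± 14.3.

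DNA replication genes were higher by a median of 0.23 over 38 genes, 21 of them above both EGFP tumors and 0 significant over the list alone (limma's camera, adjusted p = 9.77e-05, and adjusted p = 0.623 with an estimated correlation). Rfc4, a clamp loader subunit, read 410 ± 4.53 against 706 ± 118, and the helicase subunit Mcm3 656 ± 4.74 against 996 ± 156. Without EGFP tumor 2 the median was 0.13 (limma's camera, adjusted p = 0.0278). Mitotic genes had a median of 0.17 over 38 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.00388, and adjusted p = 0.705 with an estimated correlation), with Birc5 at 781 ± 47.5 against 1176 ± 47.8. That call was lost without EGFP tumor 2 (median -0.01) and without p62-EGFP tumor 1 (median 0.08; limma's camera, adjusted p = 0.801 and 0.0708), while the median was 0.43 without EGFP tumor 1 and 0.27 without p62-EGFP tumor 2. Epithelial genes had a median of 0.43 over 22 genes, 10 above both EGFP tumors and 0 significant over the list alone (limma's camera, adjusted p = 0.00282, and adjusted p = 0.623 with an estimated correlation). The keratin gene Krt19 read 125 ± 44.3 against 337 ± 5.94. The call was lost without EGFP tumor 2 (median 0.18) and without p62-EGFP tumor 2 (median 0.28; limma's camera, adjusted p = 0.282 and 0.0592), while the median was 0.84 without EGFP tumor 1. Epithelial and mitotic genes were lower in EGFP tumor 2 than in EGFP tumor 1 (median log2 differences of -0.66 and -0.35), whereas macrophage genes were higher there (3.01). Proteasome subunits had a median of 0.09 over 33 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.0233, and adjusted p = 0.623 with an estimated correlation), with Psmb3 at 635 ± 19.02 against 942 ± 52.96. That call was lost without EGFP tumor 1 (median 0.12) and without p62-EGFP tumor 1 (median 0.05; limma's camera, adjusted p = 0.432 and 0.123). It was also lost with quantile normalization (median 0.07) and with chromosome medians subtracted (median 0.01; limma's camera, adjusted p = 0.0694 and 0.508). The median was 0.16 without EGFP tumor 2 and 0.17 without p62-EGFP tumor 2.

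**Figure D2:**
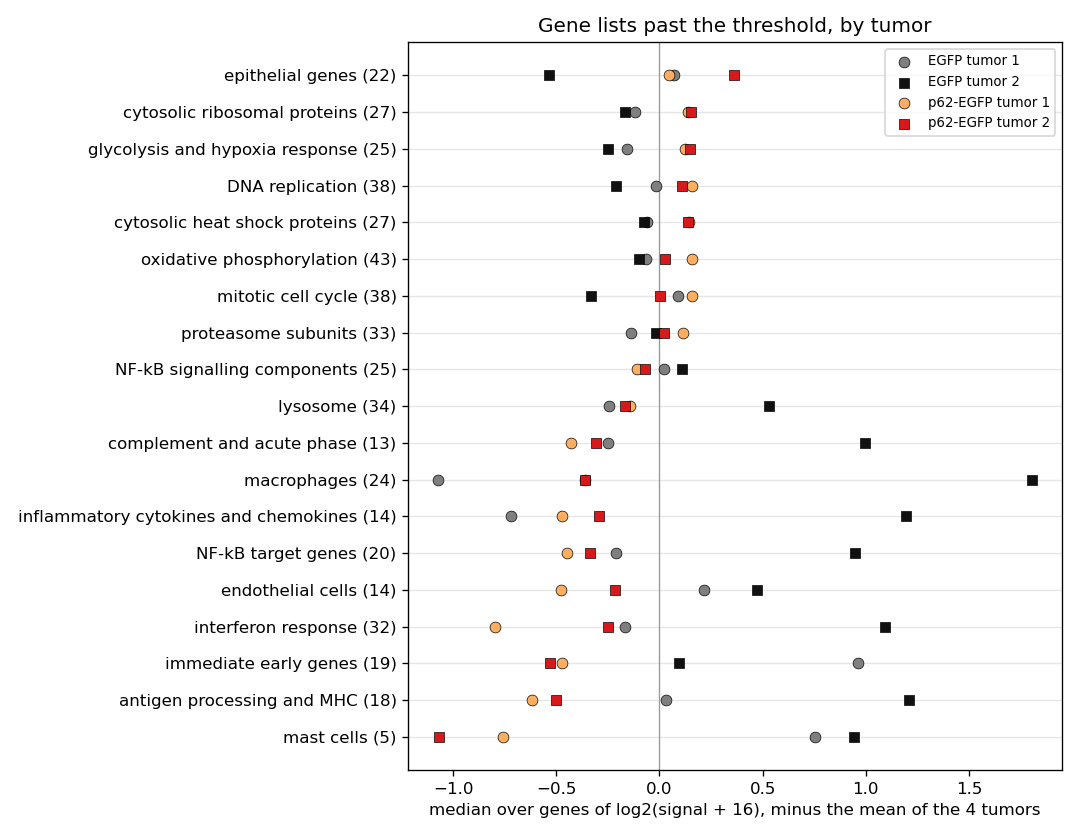
Gene lists past the camera threshold with the preset correlation, with the number of genes in brackets; each point is 1 tumor's median over the list of log2(signal + 16), after subtracting each gene's mean over the 4 tumors. EGFP tumor 2 lies at 1.81 for macrophages and 0.95 for NF-kB targets, far from the other 3 tumors, whereas both EGFP tumors lie above both p62-EGFP tumors for mast cells and immediate early genes.

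Lists tied to other roles of p62 did not pass with all 4 tumors in the fit. Targets of NRF2, the antioxidant transcription factor that p62 can release from KEAP1, had a median of 0.14 over 28 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.336). The median was 0.07 without EGFP tumor 1 and 0.21 without EGFP tumor 2 (limma's camera, adjusted p = 0.995 and 0.0662). Gstm5 read 469 ± 35.6 against 782 ± 47.9 in p62-EGFP tumors, whereas Gclm, a subunit of the glutathione-synthesis enzyme, read 238 ± 15.6 against 151 ± 12.4 and Nfe2l2, which encodes NRF2, 347 ± 14.9 against 237 ± 9.83. Autophagy genes had a median of 0.00 over 27 genes (limma's camera, adjusted p = 0.336), and 2 were higher over the list alone. These were Rb1cc1, a subunit of the ULK1 kinase complex (164 ± 3.04 against 316 ± 4.38), and Nbr1, an autophagy receptor related to p62 (573 ± 68.9 against 938 ± 27.6). Nbr1 lies on chromosome 11, whose 697 genes had a median log2 difference of 0.30. ER stress genes had a median of -0.16 over 32 genes (limma's camera, adjusted p = 0.138), with Atf4 at 742 ± 49.1 against 474 ± 36.6 and Canx at 939 ± 63.6 against 1310 ± 35.0. The medians were 0.04 for p53 targets, 0.18 for DNA damage genes and -0.05 for apoptosis regulators (limma's camera, adjusted p = 0.666, 0.119 and 0.228), with 0 members of these 3 or of the ER stress list significant over the list alone. Without EGFP tumor 1 the lists of ER stress (median -0.15), DNA damage (0.27) and apoptosis (-0.13) did pass (limma's camera, adjusted p = 0.0302, 0.0321 and 0.0321). They did not without EGFP tumor 2, with medians of 0.01, -0.05 and -0.06 (limma's camera, adjusted p = 0.797, 0.726 and 0.763).

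Mesenchymal genes went both ways (median 0.05 over 26 genes, mean -0.03, test direction downward, limma's camera adjusted p = 0.808). Over the list alone 3 were higher, among them the matrix genes Ccn2 (135 ± 2.76 against 344 ± 44.97) and Postn (167 ± 48.2 against 515 ± 13.9), and 4 were lower, among them Tgfb1 (254 ± 16.2 against 120 ± 1.48) and Lgals1 (3003 ± 262 against 1735 ± 338). Of the lipid synthesis list (median -0.04 over 27 genes, limma's camera adjusted p = 0.691), Acly was higher over the list alone and Msmo1, of cholesterol synthesis, and Srebf2, a transcription factor that drives it, were lower, at 133 ± 7.78 against 67.2 ± 2.05 and 147 ± 4.88 against 79.8 ± 2.62. Fibroblast and matrix genes had a median of 0.17 over 25 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.594). The median was 0.78 without EGFP tumor 2 and -0.32 without EGFP tumor 1 (limma's camera, adjusted p = 6.98e-09 and 0.0137). Pericyte and smooth muscle genes had a median of -0.22 over 7 genes (limma's camera, adjusted p = 0.601), with Rgs5 lower and Tagln higher over the list alone. The sign of that median was not stable: it was 0.26 without EGFP tumor 1 and 0.02 with quantile normalization. Adipocyte genes had a median of -0.14 over 9 genes, 0 of them significant over the list alone (limma's camera, adjusted p = 0.138). Lists with fewer than 5 tested genes were not tested: B and plasma cells (Ighm and Cd22), neutrophils (Fpr2), erythroid cells (Car2) and keratinocytes (Krt10 and Lor).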

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

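Among 19 Affymetrix control probe sets that detect mouse RNA and lay outside the main comparison, 5 read higher in both p62-EGFP tumors than in either EGFP tumor, with group means more than 1.5 times apart. All 3 control probe sets of the transferrin receptor were among them. The 3' probe set read 133.5 ± 10.0 in p62-EGFP and 56.5 ± 4.67 in EGFP tumors, the middle one 38.65 ± 11.5 and 11.25 ± 0.64, and the 5' one 48.4 ± 6.65 and 16.5 ± 1.70 (SD, n = 2). In the main table the probe sets of Tfrc, the transferrin receptor gene, chosen here after these values were seen, were 0.91 to 1.07 higher on the log2 scale and did not pass (limma adjusted p = 0.184 to 0.196). Of the repeat-element controls, 1 probe set of the murine B2 repeat read 494.55 ± 71.6 in p62-EGFP and 246.85 ± 10.7 in EGFP tumors, and the murine B1 repeat 2175.8 ± 46.0 and 1348 ± 434. Another B2 probe set read 4565.7 and 4507.5 in the p62-EGFP tumors and 4723.2 and 4383.9 in the EGFP tumors. No test was run on these control probe sets.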

How the results depend on the processing

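The count of probe sets that rose, 8, was 4 with a pseudocount of 1, 3 without a filter, 4 with the filter at the 60th percentile, 13 with robust eBayes and 5 with the probe sets of a gene averaged. The count that fell, 4, was 12 with robust eBayes, and the count at an unadjusted p below 0.05, 1970, was 1243 with probe sets averaged, where 8783 units were tested, probe sets without a single gene among them. Leaving out each tumor gave 0 to 1513 probe sets that rose, 0 to 1322 that fell, 514 to 4823 at an unadjusted p below 0.05, 6 to 9 lists higher and 4 to 14 lists lower; the 4 came without EGFP tumor 2. In these fits a lone tumor is assumed to vary like the other group's pair. No list passed in either direction (0 and 0) with an estimated correlation or with fry. Median centring, which moved the median of all probe sets to 0.05 at most, moved the share of higher among probe sets at an unadjusted p below 0.05, 1186 of 1970 in the main comparison, to 69.0%, and leaving out EGFP tumor 2 moved it to 48.4%.

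Replicate numbers are shared between the groups, and the replicate differences of the groups correlated at 0.0823. The labels do not say whether tumors of the same number were handled together, and this correlation does not decide it. With the replicate block 14 probe sets rose and 23 fell.

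By the direction of the test, which can differ from the sign of a list's median, these results turned. Without EGFP tumor 2, 8 lists turned, given here with the range of medians over the fits that each left out 1 tumor: lysosome (-0.718 to 0.0905, turned at 0.0905), p53 targets (-0.151 to 0.200, turned at -0.151), complement (-1.36 to -0.0932, at -0.0932), cytokines (-1.31 to 0.364, at 0.364), mesenchymal (-0.0336 to 0.135, at 0.135), lipid synthesis (-0.0424 to 0.0682, at 0.0493), macrophages (-2.12 to 0.729, at 0.729) and adipocytes (-0.516 to -0.0858, at -0.0858). Fibroblasts (-0.322 to 0.781) turned without EGFP tumor 1 at -0.322, lipid synthesis also without p62-EGFP tumor 2 at 0.0682, adipocytes without a filter at -0.0366 and mesenchymal genes with fry at 0.0533. The cause was not tested. Over the settings that kept all tumors, 389 list results kept direction and call, 42 lost the call (19 each with an estimated correlation and with fry, and the proteasome list with quantile normalization, without the trend, with probe sets averaged and with chromosome medians subtracted), 8 gained it (NK and T cells 6, skeletal muscle without a filter and adipocytes with the replicate block) and 2 turned. In the fits without 1 tumor 96 list results kept direction and call, 9 lost the call, 9 gained it and 10 turned. For named genes 241 results kept direction and call, 9 lost the call and 17 gained it; with no filter Cntn1, Zcchc18 and Tesc did not pass, nor did Zcchc18 and Tesc with a pseudocount of 64, nor Tesc with a pseudocount of 1, quantile normalization, probe sets averaged, chromosome medians subtracted or either p62-EGFP tumor left out, where Xist did not pass either. In the fits without 1 tumor 52 named-gene results kept direction and call, 4 lost the call (Xist and Tesc, each without either p62-EGFP tumor) and 37 gained it. Below the filter, and so not tested, were Cntn1 and Zcchc18 without either p62-EGFP tumor, Zcchc18 with a pseudocount of 1 or chromosome medians subtracted, and all 3 with the filter at the 60th percentile. Subtracting chromosome medians, chosen after seeing the data, left 9 of the 11 probe sets tested there and 18 of 19 lists past the threshold. The mast cell list kept fewer than 5 tested genes without either EGFP tumor, with a pseudocount of 1 and with the filter at the 60th percentile, and could not be tested. Dim probe sets limit the comparison, since values under the pseudocount of 16 carry little information.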

Other observations

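The tests of 1 chromosome's genes against a few strong genes and against array bias were set before their results were seen, and the gene list tests and the count of probe sets past the threshold belong to the planned comparison; the other tests of chromosomes, Xist, EGFP tumor 2 and splits of the arrays were chosen after the pattern was seen.

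Transcripts of skeletal muscle stood high in p62-EGFP tumor 1 and low in the other p62-EGFP tumor. Mylpf, a fast muscle myosin light chain, read 15.0 and 70.2 in EGFP tumors 1 and 2 and 508.5 and 20.5 in p62-EGFP tumors 1 and 2. Atp2a1, the calcium pump of fast muscle, read 9.7, 49.5, 301.9 and 13.8, and Ttn, which encodes titin, 4.7, 43.2, 262.9 and 6.1. The median over 11 muscle genes was 19.01-fold higher in p62-EGFP tumor 1 than in tumor 2, and 0 of them differed between the groups over the list alone (median 1.17, limma's camera, adjusted p = 0.266). The list passed without p62-EGFP tumor 2 (median 3.26) and without EGFP tumor 2 (median 2.16; limma's camera, adjusted p = 6.90e-16 and 5.97e-04), and its median was 0.49 without EGFP tumor 1. Chromosome by chromosome, the genes of several chromosomes moved together. Over 697 genes of chromosome 11 the median log2 difference was 0.30, and 77.8% lay above the median of all genes, whereas 17.5% of 417 genes of chromosome 8 did (median -0.22).

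The tumors differed in the level of the genes of several chromosomes. In permutations of genes, 16 of 20 chromosomes departed from all genes at an adjusted p below 0.05. Genes were treated as independent, and 0.0001 is the smallest p that 10000 shufflings can give. For 10 of the 16 all 4 tumor pairs lay on 1 side of all genes, and the count over all 20 chromosomes was also 10. The pairs share the same 4 tumors, and chance sets the groups apart for a single value in 16.7% of cases each way. The count of 10 alone therefore does not decide whether the shifts go with the groups. The SD of the 20 chromosome medians was 0.138, above the highest of 10000 shufflings, 0.0378, which argues against chance placement of changed genes. Without genes at an unadjusted p below 0.05 and without listed genes, chromosome 11 still stood 0.181 above all genes. The 95% bootstrap interval was 0.158 to 0.207 over 423 genes, against 0.289 for all genes of the chromosome. A few strong genes hardly move a median of 697 genes, so that test could hardly come out otherwise. It shows only that genes without a strong change shared the shift. After matching on mean signal the value was 0.285, so a bias that depends on mean signal does not account for it. Other forms of array bias were not tested. All 10 of 10 consecutive blocks of chromosome 11 lay above the median of all genes, by an uneven 0.0266 to 0.405. A different copy number of that chromosome in the cells could give this, but the hypothesis was found and tested on the same data. With 77.8% of the chromosome's genes above that median, most blocks were likely to lie above it, so the count decides little. Of the 16 chromosomes 8 had all or none of their blocks above it. The other 8 had 1 to 9, as did chromosome 3 (9 of 10), which did not depart. Chromosome medians also differed between the EGFP tumors (SD 0.183) and less between the p62-EGFP tumors (SD 0.0864). The SD of the EGFP pair, taken between single tumors, was above the 0.138 between group means, so shifts of that size also arose within a group. Whether p62 or separate descent of the cell populations goes with the shifts between the groups was not tested.

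All 3 Xist probe sets read 350.9 or more in both p62-EGFP tumors and 34.6 or less in both EGFP tumors, although the cell lines are described as isogenic. A second active X chromosome in the EGFP tumor cells would put X-linked genes higher there, but the median of X genes without Xist was 0.04 (0.0394879), on the side of the p62-EGFP tumors. A Y chromosome in the EGFP cells stays open. The Y-linked gene Eif2s3y read 5.5 and 59.5 in EGFP tumors 1 and 2 and 5.1 and 7.0 in p62-EGFP tumors. It thus stood out only in EGFP tumor 2, where macrophage transcripts were high, and whether tumor or host cells gave this signal was not tested. The other Y-linked probe sets read 16.1 or less in every tumor. No array of known male tissue shows what level to look for. If all mice were female, host cells would bring Xist into EGFP tumor 2 as well, but its 3 probe sets read 0.2, 5.1 and 13.7 there. Macrophage genes were lower in the p62-EGFP tumors than in EGFP tumor 2, by a median log2 difference of -2.12. Xist from female host cells in the p62-EGFP tumors thus stays open only for hosts of different sex. The sex of the mice is not given in the sources used here. The Xist signal was 1.04-fold (1.04329) in p62-EGFP tumor 2 relative to tumor 1. Macrophage, endothelial and fibroblast transcripts differed too little between these tumors for that to decide. Cells of different origin or loss of Xist in the EGFP line are biological candidates, as is p62 itself, and none was tested.

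NF-kB target, macrophage and NK cell transcripts stood high in EGFP tumor 2. Its spike-in controls were 0.789 times as bright as those of EGFP tumor 1. All arrays were scaled to the same trimmed mean signal, so this ratio cannot tell whether array brightness plays a part. Of the macrophage genes 95.8% (23 of 24) were 2-fold or more higher than in EGFP tumor 1, with a median of 8.08-fold, and NK and T cell genes had a median of 15.0-fold; these are the transcripts that make up the pattern, so more host immune cells in that tumor stay open as its explanation. A lower share of all host cells in the p62-EGFP tumors stays open too: the log2 medians of macrophage and fibroblast genes were 0.711 and 0.781 against EGFP tumor 1 but -2.12 and -0.322 against EGFP tumor 2, while those of mast cell and endothelial genes were -1.60 and -0.45 against EGFP tumor 1 and -1.79 and -0.89 against EGFP tumor 2. With 2 tumors per group, whether infiltration differs with p62 or between single tumors stays open.

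The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real groups gave 12 probe sets past the threshold and were the 1 split of 3 to give as many; the highest of the other splits gave 0. At an unadjusted p below 0.05 with limma the real groups gave 1970 probe sets and the other splits 241 and 102.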
